A study of Homo sapiens with 9 samples.

How the data were processed

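The samples were 9 libraries of poly(A)-enriched RNA from THP-1 cells, per the labels' protocols, in 3 groups of 3. Groups were taken from the sample titles. The replicate numbers run from 1 to 9 across the groups, so that no number is shared. The authors deposited 1 table with FPKM values for 34643 Ensembl genes, with 1 column per library. FPKM are fragments scaled to a length of each gene and to a fragment total of the library. The submitters' processing notes name bcl2fastq, FastQC, HISAT2, StringTie and the build GRCh38, without versions, and do not say how fragments were assigned to genes, whether strand was used or how reads that fit several genes were treated. Levels of near-identical copies and of overlapping or antisense genes are therefore uncertain. Coordinates are those of the deposited table. Of its gene IDs 34579 (99.8%) are in GENCODE v29, 98.5% of them at the same position.

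FPKM values carry no depth of their own. Multiplied by the total exon length of each gene in GENCODE v29 and divided by the value of 1 fragment in that library, 97.6 to 97.7% of the values came out as whole numbers within a tolerance of 0.05. This points to scaling by total exon length rather than by the length of a single transcript. The value of 1 fragment gave a depth of 15641354 to 17875225 fragments per library. The 10 most abundant genes held 12.8 to 13.6% of the summed FPKM in each library. For a gene with no fragment in control, a bound was set at 3 fragments per control library; such floors cover counting error only, and without molecular identifiers fragments are not independent molecules. The duration of the LPS and PD exposure and any vehicle are not given in the sources used here. The design text also names the lung epithelial line A549, of which no library was analysed here.

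Differences between groups were computed from the deposited FPKM values with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), over the 13692 genes with an FPKM of at least 1 in at least 3 of the 9 libraries. One model held the 3 group means, so that all groups shared the estimate of the spread, and the 3 contrasts were tested with eBayes with an intensity trend. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. Fold changes are on the log2(FPKM + 1) scale. Levels are given as mean FPKM, with the SD over 3 libraries where it is printed. Single genes of the TNF and IL7 axis were also tested with a two-sided exact permutation test. Gene lists (33, fixed before the data were examined) were tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Fry's directional p tests whether a list's genes move on balance one way and does not compare the list with other genes.

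Genes named in the text follow a rule fixed before the data were examined. It took the 8 largest rises and 8 largest falls of each of the first 2 comparisons and the 4 largest of each in the third, among genes called, with no overlap between the groups' libraries and a mean FPKM of at least 5 in one of the groups. It added 12 genes fixed by name, up to 4 members with the smallest p per list, the 10 genes moved back most and the 5 moved further most. Clone names, duplicated symbols and genes on the Y chromosome were left out. Some genes that the rule takes are not reported here. Other genes named are said to have been chosen after their values were seen.

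The gene test was checked on simulated fragments drawn at the real means and depths with 200 genes changed in the LPS group and a dispersion of 0.001. For LPS against control it recovered 48.0% of 50 genes changed 1.2-fold, 94.0% at 1.5-fold, 98.0% at 2-fold and 98.0% at 4-fold, and called 11 of 13084 unchanged genes. For LPS+PD against LPS it recovered 46.0%, 96.0%, 98.0% and 98.0% at these sizes and called 9 unchanged genes. The simulation gave all genes the same dispersion and changed few of them, whereas 66.2% of the tested genes were called for LPS against control. It therefore does not show how many calls depend on the scaling between libraries. Alternatives covered the pseudocount, the filter on low values, the scaling between libraries, the libraries in the fit, the spread estimate, array weights, the thresholds, duplicated symbols, the list test and each library left out in turn. Chosen after seeing the data were limma voom on the recovered fragments and a restriction to protein-coding genes.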

Results

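Gene expression was measured by sequencing of poly(A)-enriched RNA in THP-1, a human monocytic leukaemia cell line. The phorbol ester PMA pushes this line towards a macrophage state. Per the labels, the cells were first given PMA at 500 nM for 4 h and were then rested for 24 h. They fell into 3 groups of 3 libraries, which were an untreated control (replicates 1 to 3), LPS, a bacterial cell wall component that activates macrophages, at 1 µg/mL (replicates 4 to 6), and the same dose of LPS with 10 µM PD (replicates 7 to 9). The title of the series gives PD as panaxadiol, a plant triterpenoid, and ties it to inflammation through TNF and IL7 and their receptors. No group received PD alone. The depth implied by the deposited FPKM values was 15641354 to 17615433 fragments in control libraries, 16218731 to 17666866 in LPS libraries and 16974321 to 17875225 in LPS+PD libraries. In each library 12458 to 13056 genes reached an FPKM of 1.

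The libraries separated by treatment. The first principal component held 80.4% of the variance, with control libraries near -53, LPS libraries from 38.7 to 43.2 and LPS+PD libraries from 10.7 to 12.2. On the second component, which held 6.57%, the LPS+PD libraries lay at -14.4 to -16.1, apart from the control libraries at 4.74 to 4.95 and the LPS libraries at 7.72 to 12.0. Within a group the correlation between libraries across genes was at least 0.989. Every pair within a group still differed by more than sampling noise, with a chi-square per degree of freedom of 2.37 to 3.55 over recovered fragments, so all 9 were counted as separate libraries.

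**Figure D1:**
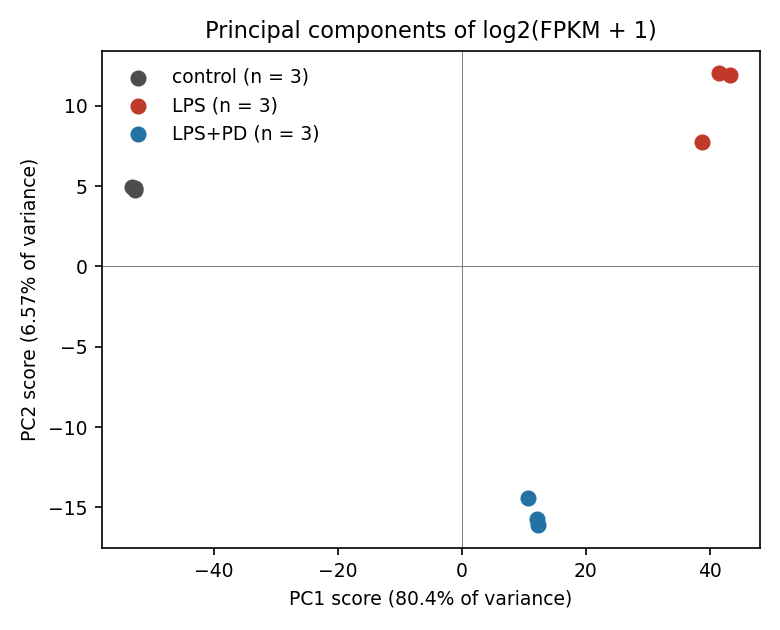
Principal components of log2(FPKM + 1) over the 13692 tested genes, with 1 point per library and colours for the 3 groups (n = 3 each). Axes are scores of the first and second component, and the LPS+PD libraries lie between control and LPS on the first and below both on the second.

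The first comparison, LPS against control, asked what LPS did to these cells. Each gene named as raised in this paragraph went from an FPKM below 1 in control to over 100 with LPS, and most of these genes encode cytokines or chemokines. Other chemokine genes reached lower levels with LPS, such as CCL8 at 32.5 and CCL1 at 18.4 FPKM. IL1B, a cytokine released after inflammasome activation (ENSG00000125538, GRCh38 chromosome 2, 112829751 to 112836903, minus strand), went from an FPKM of 0.235 ± 0.0275 to 478 ± 101 (SD, n = 3). EBI3, a subunit shared by regulatory cytokines, rose from 0.282 to 452, the B-cell chemokine CXCL13 from 0.0430 to 345 and IGFBP3, which binds insulin-like growth factors, from 0.168 to 323. Further rises were those of the monocyte chemokine CCL2 from 0.113 to 245, the secreted oxidase IL4I1 from 0.614 to 229 and the neutrophil chemokine CXCL8 from 0.470 to 167. CCL4L2 had no fragment in any control library and a mean FPKM of 171 with LPS, at least 1243-fold above a floor of 3 fragments per control library. CCL4L2 and CCL3L1 are near-identical to CCL4 and CCL3, so reads may be split between the copies and their single levels are uncertain. The largest falls were in SERPINB2, a protease inhibitor (33.0 to 0.465), MS4A3, a membrane protein of granulocyte-monocyte precursors (69.6 to 2.38), the noncoding LINC02169 (142 to 6.92) and SERPINB10 (13.001 to 0.356). Also among them were F13A1, a coagulation factor subunit (10.1 to 0.175), the granule protease CTSG (1360.4 to 143), MYADM (35.4 to 2.89) and B3GNT7 (17.1 to 1.12). Their log2 fold changes ran from -4.54 for SERPINB2 to -3.09 for B3GNT7, on the log2(FPKM + 1) scale, which understates changes of low genes.

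Across the lists fixed in advance, all 41 tested type I interferon-stimulated genes rose (median log2 fold change 3.43, camera adjusted p = 4.33e-29). Among them IFI6 went from 22.3 to 1358 FPKM, OAS3, a sensor of double-stranded RNA, from 3.13 to 151 and the chemokine CXCL10 from 0.0357 to 88.5. Of 28 NF-kB target and feedback genes 27 rose (median 3.04, adjusted p = 2.77e-18), including ICAM1 (0.478 to 85.9), SOD2 (2.86 to 74.9), NFKBIA (16.2 to 218) and TNFAIP3 (3.63 to 71.9). Inflammatory cytokines rose in 13 of 14 (median 1.97), CC chemokines in 12 of 14 (median 3.72) and CXC chemokines for neutrophils in 3 of 3 (median 4.10, adjusted p = 0.0615 with an estimated correlation). IL6 had no fragment in control libraries and a mean FPKM of 2.77 with LPS, at least 29.9-fold above the floor of 3 fragments per library. The counts of the 5 lists above were identical when adjusted over the list alone.

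Macrophage markers rose in 17 of 21 and fell in 2 (3 when adjusted over the list alone), among them CD14, the LPS co-receptor, from 0.466 to 35.1. All 14 myeloid progenitor markers fell (median -1.56, camera adjusted p = 5.78e-07, and adjusted p = 0.0615 with an estimated correlation), among them the granule proteins PRTN3 (1281 to 268) and CTSG and the proteoglycan SRGN (2572 to 836). In the control libraries PRTN3 was thus high, at 1281 FPKM, and CD14 low, at 0.466. No library without PMA was among the samples, so how far control cells had moved towards a macrophage state was not tested. All 32 ribosomal protein genes fell, by a median of -0.65 (adjusted p = 1.10e-09), with RPL5 at 499 in control and 280 with LPS; that list had an adjusted p = 0.217 with an estimated correlation. Cell cycle genes fell in 22 of 30 and rose in 4, or 5 when adjusted over the list alone (median -0.28, adjusted p = 0.00995, and adjusted p = 0.217 with an estimated correlation). Of 13 mitochondrially encoded genes 11 fell (median -0.22, adjusted p = 0.01999, and adjusted p = 0.352 with an estimated correlation). That call was lost under median-of-ratios scaling (adjusted p = 0.0885) and under quantile normalization (adjusted p = 0.203).

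Antigen presentation and stress lists moved upwards. MHC class I presentation genes rose in 16 of 18, with TAP1, a peptide transporter subunit, from 13.2 to 77.1, and MHC class II presentation genes in 7 of 10, with HLA-DRA from 8.42 to 88.3; HLA genes share reads with one another. All 6 metallothionein list members rose, with the metal-binding MT2A from 9.33 to 242, and 18 of 20 NRF2 antioxidant genes rose, with the iron-storage gene FTH1, which has many pseudogene copies, from 65.6 to 1756 and HMOX1, which degrades haem, from 0.562 to 15.4. Glucocorticoid receptor targets rose in 9 of 10, matrix metalloproteinases and inhibitors in 8 of 10 (MMP9 from 0.0177 to 105), the LPS receptor pathway in 13 of 21, TNF receptor signalling in 17 of 30 and ATF4 and unfolded protein response genes in 17 of 28. These 9 lists and macrophage markers kept their calls with an estimated correlation, and adjusted over the list alone the counts of the 9 did not differ. With a filter at an FPKM of 5 the metalloproteinase list lost its call (adjusted p = 0.207). A further 8 lists were called upwards only with the preset correlation. They were hypoxia and glycolysis genes (21 of 25 rose, PKM from 74.1 to 257, adjusted p = 0.0615 with an estimated correlation), immediate early genes (16 of 18 rose, adjusted p = 0.0615), and cholesterol synthesis (19 of 24, adjusted p = 0.0615). The others were IL7 receptor signalling (11 of 20, adjusted p = 0.0615), the inflammasome list (10 of 17, adjusted p = 0.0615), p53 targets and apoptosis (12 of 18, adjusted p = 0.1002), prostaglandin and leukotriene synthesis (8 of 14, adjusted p = 0.1002) and heat shock proteins (7 of 15, adjusted p = 0.170), each p with an estimated correlation. With a filter at an FPKM of 5 the lists of IL7 receptor signalling (adjusted p = 0.0540) and heat shock proteins (adjusted p = 0.0760) lost their calls, the latter also with protein-coding genes alone (adjusted p = 0.0579). Adjusted over the list alone, only IL7 receptor signalling differed among these, with 6 falling genes in place of 5. Not called by camera were the lists of liver X receptor targets (7 of 13 fell, 8 when adjusted over the list alone), nuclear oxidative phosphorylation genes (18 of 34 fell), alternative activation markers (5 of 9 rose; called without a filter on low values, adjusted p = 0.0198), and the markers of other cell types. Of these, 3 of 5 fibroblast and endothelial markers rose and 1 fell, 2 of 4 lymphocyte markers rose and 2 fell, and 2 of 3 epithelial markers rose and 1 fell, with 3 of the 26 fixed epithelial members tested. Fry, which does not compare a list with other genes, called 32 of the 33 lists. Among them were liver X receptor targets (adjusted p = 5.85e-05), oxidative phosphorylation genes (adjusted p = 0.00543) and the fibroblast and endothelial (adjusted p = 1.94e-05), lymphocyte (adjusted p = 5.51e-07) and epithelial markers (adjusted p = 0.00163).

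The test, limma with an intensity trend on log2(FPKM + 1), called 9059 of 13692 genes at an adjusted p below 0.05, of which 3621 were higher and 5438 lower with LPS. At least a 2-fold change on that scale was seen in 886 and 720 of them. Scaling by median-of-ratios size factors, which by construction sets the median change near 0 and so favours an even split, gave 4528 higher and 4418 lower. The 3 libraries of each group did not overlap in 69.8% of the genes, against 10% by chance. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

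The second comparison, LPS+PD against LPS, asked what PD changed in LPS-treated cells. The largest falls with PD included LPS-induced chemokine and cytokine genes. CCL2 (chromosome 17, 34255218 to 34257203, plus strand) fell from 245 ± 20.4 to 27.7 ± 1.15 FPKM (log2 fold change -3.10, SE 0.06, limma adjusted p = 8.74e-09) and IL1B from 478 ± 101 to 51.6 ± 1.72. The monocyte chemokine CCL8 went from 32.5 to 2.43, CCL1, a T-cell and monocyte chemokine, from 18.4 to 0.677, CCL4L2 from 171 to 14.2, CCL3L1 from 152 to 14.1, CXCL13 from 345 to 39.5 and IDO1, which degrades tryptophan, from 23.0 to 2.21. The rises were smaller. TIMP3, an inhibitor of metalloproteinases, rose from 2.78 to 10.5, the pro-apoptotic BIK from 6.80 to 19.6, LINC02169 from 6.92 to 18.8, carbonic anhydrase CA2 from 143 to 335, CCDC88B from 8.45 to 20.9 and the receptor phosphatase PTPRF from 8.05 to 19.9, all of which had been higher still in control. The surface glycoprotein CD52 rose from 5.23 to 14.3, against 4.99 in control. IGKC, an immunoglobulin constant-region gene, rose from 1.05 to 5.31 with 34 to 62 fragments in each LPS+PD library and none in control.

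All 41 interferon-stimulated genes fell with PD (median log2 fold change -1.19, camera adjusted p = 1.64e-41), for example IFIT1 from 33.9 to 9.68 and IFI44L from 32.5 to 8.77. All 28 NF-kB target and feedback genes fell, by a median of -0.69 (adjusted p = 1.75e-21). Within that list the size varied, with TNIP3 (6.11 to 0.529), TRAF1 (20.3 to 4.01) and NFKBIA (218 to 158) as examples. CC chemokines fell in 12 of 14 (median -2.24), inflammatory cytokines in 12 of 14 (median -1.37), with 1 rising member when adjusted over the list alone, and CXC chemokines for neutrophils in 3 of 3 (median -1.68). IL12B, a subunit of cytokines that drive T helper cells, went from 13.4 to 1.01, the interleukin-1 receptor antagonist IL1RN from 47.5 to 13.9 and IL6 from 2.77 to 0.193. PTGS2, the inducible cyclooxygenase, fell from 1.85 to 0.561. TLR4, the LPS receptor, fell from 1.34 to 0.816, while between LPS and control its limma adjusted p was 0.577. With LPS+PD it was also called below control (log2 fold change -0.31, limma adjusted p = 0.0107), at levels close to the filter at an FPKM of 1.

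Macrophage markers fell in 13 of 21 (CSF1R from 78.6 to 41.3 and ADGRE1 from 8.26 to 1.63) and rose in 3, among them TREM2, a lipid-sensing receptor, from 19.8 to 44.8. Falls also outnumbered rises for IL7 receptor signalling (11 of 20 fell, with SOCS3, a feedback inhibitor of cytokine receptors, from 42.3 to 5.15), TNF receptor signalling (16 of 30) and the LPS receptor pathway (9 of 21). The same held for the inflammasome list (10 of 17; CASP5 from 4.69 to 0.561), MHC class I presentation (10 of 18; HLA-E from 76.9 to 47.2) and glucocorticoid receptor targets (8 of 10, or 10 of 10 when adjusted over the list alone). These lists, with the 5 of the paragraph above, were the 12 called with both the preset and an estimated correlation; adjusted over the list alone, the inflammasome list had 2 rising genes in place of 1 and the others, apart from those given, the same counts. Called downwards only with the preset correlation were immediate early genes (15 of 18 fell, adjusted p = 0.0519 with an estimated correlation), matrix metalloproteinases and inhibitors (5 of 10, 6 when adjusted over the list alone, adjusted p = 0.0512), cholesterol synthesis (15 of 24, adjusted p = 0.0580) and ATF4 and unfolded protein response genes (11 of 28, adjusted p = 0.0832). The others were hypoxia and glycolysis genes (12 of 25, or 15 when adjusted over the list alone, adjusted p = 0.101), prostaglandin and leukotriene synthesis (7 of 14, adjusted p = 0.108), fibroblast and endothelial markers (3 of 5, adjusted p = 0.125) and p53 targets and apoptosis (8 of 18, 9 when adjusted over the list alone, adjusted p = 0.215; CDKN1A, a cell cycle inhibitor, from 95.5 to 36.9), each p with an estimated correlation. Rising members adjusted over the list alone were 3 in place of 2 for cholesterol synthesis, 6 in place of 4 for ATF4 and unfolded protein response genes and 7 in place of 6 for p53 targets. With a filter at an FPKM of 5 the calls of the metalloproteinase list (adjusted p = 0.234), prostaglandin and leukotriene synthesis (adjusted p = 0.0810) and ATF4 and unfolded protein response genes (adjusted p = 0.0511) were lost.

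The 4 lists called upwards with PD had all fallen, or in the case of nuclear oxidative phosphorylation genes not been called, in LPS against control. Myeloid progenitor markers rose in 11 of 14 (13 when adjusted over the list alone; median 0.49, adjusted p = 0.0848 with an estimated correlation), with CLEC11A, a growth factor for progenitor cells, from 301 to 507 and the transcription factor MYB from 28.8 to 43.9. Cell cycle genes rose in 21 of 30 (24 when adjusted over the list alone; median 0.20, adjusted p = 0.0805 with an estimated correlation), with the helicase subunit MCM4 from 70.6 to 92.9 and TYMS, an enzyme of thymidine synthesis, from 38.2 to 51.8. Oxidative phosphorylation genes rose in 21 of 34 (22 when adjusted over the list alone; median 0.16, adjusted p = 0.225 with an estimated correlation) and ribosomal protein genes in 24 of 32 (27 when adjusted over the list alone; median 0.14, adjusted p = 0.437 with an estimated correlation). Not called by camera were NRF2 antioxidant genes (6 of 20 fell and 4 rose; called with median-of-ratios scaling, adjusted p = 0.0493, and with voom, adjusted p = 0.0364) and metallothioneins (3 of 6 fell; called without a filter on low values, adjusted p = 0.0194). Nor were MHC class II presentation (4 of 10 rose, CD74 from 139 to 168, and 2 fell, or 3 when adjusted over the list alone), heat shock proteins (5 of 15 rose), liver X receptor targets (3 of 13 rose), alternative activation markers (3 of 9 fell), mitochondrially encoded genes (5 of 13 rose; called without a filter on low values, adjusted p = 0.00438, and with voom, adjusted p = 0.0176), lymphocyte markers (2 of 4 fell and 1 rose; called with voom, adjusted p = 0.0364) and epithelial markers (1 of 3 rose, or 2 when adjusted over the list alone, and 1 fell). The medians of heat shock proteins, MHC class II presentation and alternative activation markers were 0.04, 0.05 and 0.02, and -0.04, -0.03 and -0.04 with median-of-ratios scaling. For alternative activation and epithelial markers the median and the camera test differed in sign. Fry called 31 of the 33 lists, all but liver X receptor targets (adjusted p = 0.0967) and epithelial markers (adjusted p = 0.785). Of the lists that camera did not call, fry thus called NRF2 antioxidant genes (adjusted p = 0.00572), metallothioneins (adjusted p = 0.00583), MHC class II presentation (adjusted p = 0.0260), heat shock proteins (adjusted p = 0.0128), alternative activation markers (adjusted p = 0.0265), mitochondrially encoded genes (adjusted p = 0.0125) and lymphocyte markers (adjusted p = 1.93e-05).

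The test called 5037 of 13692 genes, 3259 higher and 1778 lower with PD, and of these 35 and 196 changed at least 2-fold on the log2(FPKM + 1) scale. The direction of the majority depended on the scaling, since with median-of-ratios size factors 2058 genes were higher and 2508 lower. The groups' libraries did not overlap in 50.4% of the genes, against 10% by chance.

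**Figure D2:**
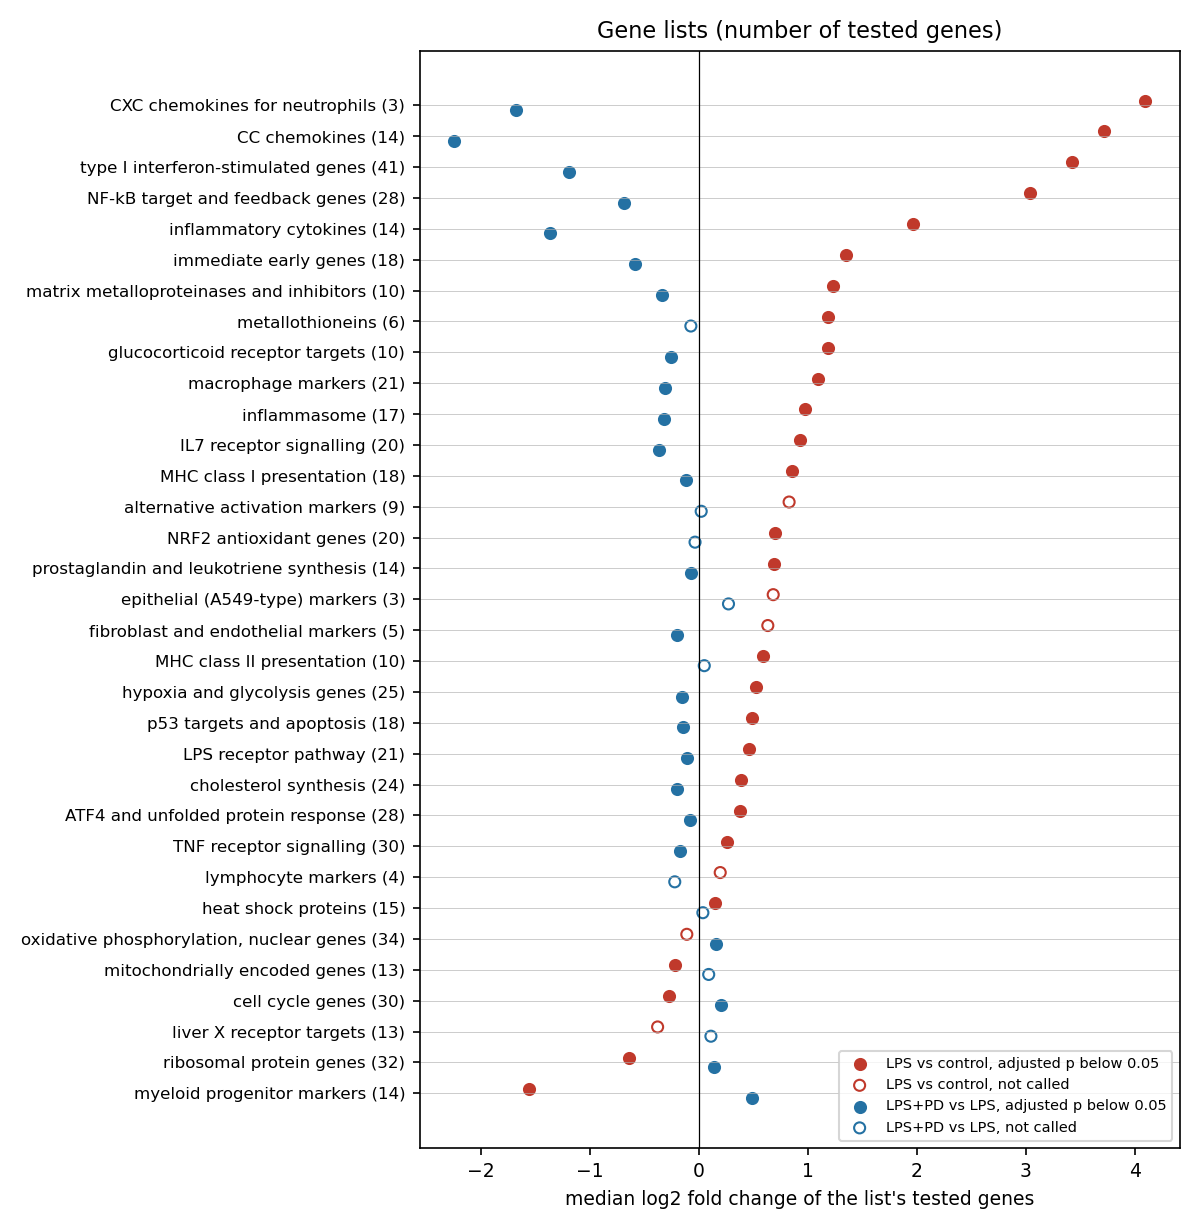
Median log2 fold change of the tested members of each of 33 gene lists (x axis), for LPS against control in red and LPS+PD against LPS in blue, with filled circles for lists at a camera adjusted p below 0.05. Interferon-stimulated genes lie at 3.43 and -1.19, CC chemokines at 3.72 and -2.24 and myeloid progenitor markers at -1.56 and 0.49.

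The series title puts the TNF and IL7 ligand and receptor genes at the centre of the study. TNF (ENSG00000232810, GRCh38 chromosome 6, 31575567 to 31578336, plus strand) was at 2.46 ± 0.0672 FPKM in control, 128 ± 7.44 with LPS and 47.2 ± 1.05 with LPS+PD (SD, n = 3). It was 52.1 times the control level with LPS and 19.1 times with LPS+PD. IL7R (ENSG00000168685, chromosome 5, 35852695 to 35879603, plus strand), a chain of the IL7 receptor, went from 0.468 ± 0.171 to 22.2 ± 2.17 and to 3.52 ± 0.185, a fall with PD of log2 fold change -2.36 (SE 0.09, limma adjusted p = 3.74e-07). TNFRSF1B (ENSG00000028137, chromosome 1, 12167003 to 12209228, plus strand), the second TNF receptor, was at 18.0 ± 0.750, 93.6 ± 3.16 and 50.9 ± 2.45. IL7 itself (ENSG00000104432, chromosome 8, 78675743 to 78805523, minus strand) stayed low, at 0.0829 ± 0.0232, 2.23 ± 0.393 and 1.09 ± 0.101. Its mean was 26.9 times the control level with LPS and 13.2 times with LPS+PD, over only 3 to 6 fragments in each control library. The LPS+PD mean of IL7 was 0.489 times that with LPS, a log2 fold change of -0.62 on the log2(FPKM + 1) scale (SE 0.11, limma adjusted p = 0.00162). TNFRSF1A (ENSG00000067182, chromosome 12, 6328757 to 6342114, minus strand), the first TNF receptor, changed least, with 23.9 ± 0.629, 27.1 ± 1.17 and 22.0 ± 1.81. It was higher with LPS than in control by 0.18 on the log2 scale (SE 0.06, limma adjusted p = 0.0214) and lower with LPS+PD than with LPS by a log2 fold change of -0.29 (adjusted p = 0.00327). LPS+PD and control were not told apart (limma adjusted p = 0.106). The rise with LPS was no longer called under quantile normalization (adjusted p = 0.139), without a filter on low values (adjusted p = 0.05001), without control replicate 1 (adjusted p = 0.0685), without LPS replicate 4 (adjusted p = 0.0603) or without LPS replicate 6 (adjusted p = 0.0716). The difference between LPS+PD and control became a call under quantile normalization (adjusted p = 0.0189) or without LPS+PD replicate 7 (adjusted p = 0.0250). In 14 of the 15 comparisons of these 5 genes the gene was called, over all genes and adjusted over the list alone. In the two-sided exact permutation test of single genes, 3 against 3 libraries cannot go below p = 0.1, the value that 14 of the 15 comparisons reached. For TNFRSF1A against control with LPS+PD it was exact p = 0.2.

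**Figure D3:**
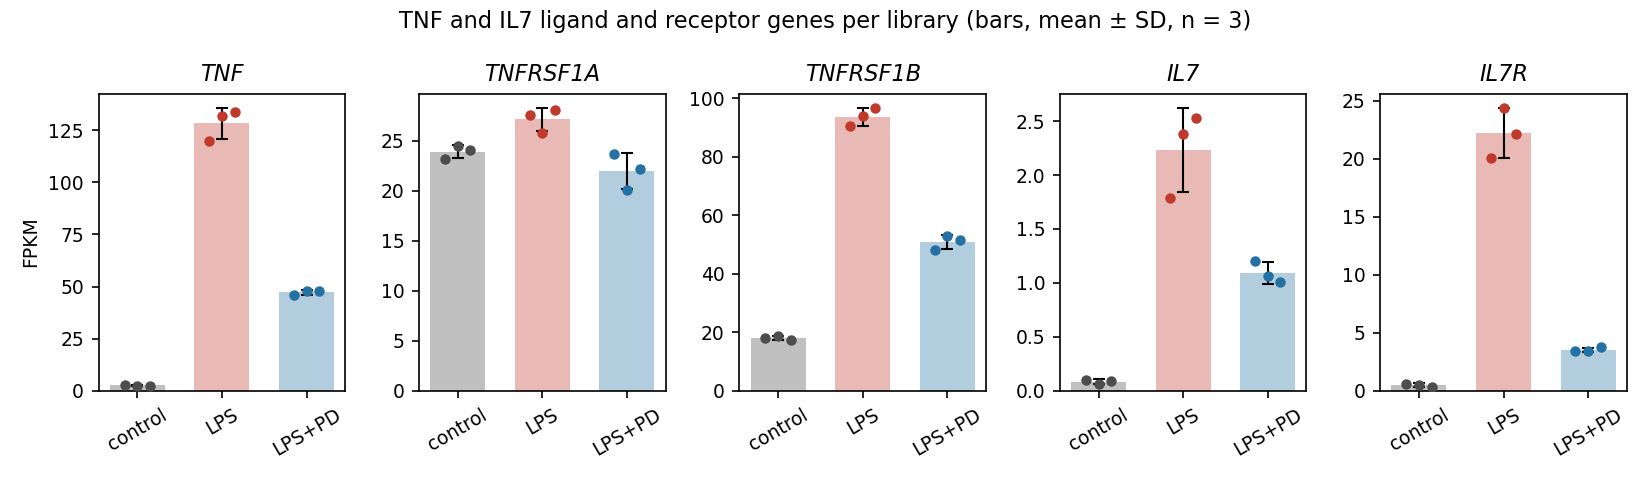
FPKM of the TNF and IL7 ligand and receptor genes in each library (points), with bars and error bars for the mean and SD of each group (n = 3), each panel with its own axis from 0. The LPS+PD libraries lie between control and LPS for all but TNFRSF1A, whose means were 23.9, 27.1 and 22.0 FPKM.

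The third comparison, LPS+PD against control, asked how much of the LPS response was present with PD. EBI3 (0.282 to 205 FPKM), IGFBP3 (0.168 to 99.0), IL4I1 (0.614 to 125) and MMP9, a secreted gelatinase (0.0177 to 65.3), had the largest rises, and MS4A3 (69.6 to 6.04), LINC02169 (142 to 18.8), SERPINB2 (33.0 to 3.96) and SERPINB10 (13.001 to 1.17) the largest falls. CXCL8 was still at 30.04 against 0.470 and CCL2 at 27.7 against 0.113. PTGS2 was not called, at 0.561 against 0.363 (limma adjusted p = 0.120), but was without an intensity trend (adjusted p = 0.0386), with voom (adjusted p = 0.0481) and with protein-coding genes alone (adjusted p = 0.0426). IL6, at 0.193 against no fragment in control, was not called (limma adjusted p = 0.124), but was with a pseudocount of 0.1 (adjusted p = 0.0168), rescaled to TPM (adjusted p = 0.0375), with voom (adjusted p = 0.000995) and with protein-coding genes alone (adjusted p = 0.0418). All 41 interferon-stimulated genes remained above control (median log2 fold change 2.27), as did 26 of 28 NF-kB target and feedback genes (median 2.23, camera adjusted p = 0.0698 with an estimated correlation). All 32 ribosomal protein genes (median -0.49, adjusted p = 0.176 with an estimated correlation) and 13 of 14 myeloid progenitor markers (median -1.10, adjusted p = 0.0698 with an estimated correlation) were below it. Mitochondrially encoded genes fell in 8 of 13 (median -0.13, adjusted p = 0.0344, and adjusted p = 0.422 with an estimated correlation), but the call was lost with median-of-ratios scaling (adjusted p = 0.0639) and with quantile normalization, where the median was 0.02 (adjusted p = 0.601). Cell cycle genes were not called by camera (7 of 30 higher, 9 lower, adjusted p = 0.628) or by fry (adjusted p = 0.275). Of 33 lists camera called 22 upwards and 3 downwards and fry called 31, and 7 of the camera calls held with an estimated correlation. These were the calls of interferon-stimulated genes, NRF2 antioxidant genes, metallothioneins, glucocorticoid receptor targets, both MHC lists and macrophage markers. The test called 7489 genes, 3556 higher and 3933 lower than control. The majority turned with the scaling, to 3833 higher and 3635 lower with median-of-ratios size factors and to 3768 higher and 3589 lower when rescaled to TPM. The groups' libraries did not overlap in 61.6% of the genes, against 10% by chance.

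Setting the first 2 comparisons side by side, 4290 genes (47.4% of those called in LPS against control) were moved back by PD, that is, called in both with opposite signs. Of these 1613 were raised by LPS and lowered with PD, and 2677 lowered by LPS and raised with PD. Only 224 were moved further in the same direction, 184 up and 40 down. Independent lists of these sizes would share 470 and 1294 genes with opposite signs, and 862 and 706 with equal signs. The 2 lists are not independent, because the shared LPS libraries favour opposite signs, so these numbers are no yardstick for the observed counts. Groups simulated without any effect had opposite signs in 66.6% of genes, called or not. The largest movements back were those of CCL1, CCL4L2, CCL3L1, CCL8, IL1B, CCL2, CXCL13, IDO1, IL12B and SOCS3, and the largest movements further those of IGKC, IGSF6 (5.90 to 11.1 FPKM), the cytokine receptor IL27RA (12.5 to 20.9), RN7SL3 (15.8 to 25.9), which has near-identical copies, and the integrin ITGAM (11.8 to 19.2). RN7SL3 had 75 to 82 fragments in each LPS library and 132 to 139 in each LPS+PD library. Among the genes moved back, 2983 were still called against control on the LPS side and 1221 were not called against control. The rest were called on the opposite side of control. In all, 86 genes called in LPS against control were called with the opposite sign in LPS+PD against control. The log2 fold changes of both comparisons had a correlation of -0.79 across genes, which are not independent replicates. The LPS libraries enter both with opposite signs, so groups simulated without any effect of LPS or PD gave -0.50 (range -0.55 to -0.44 over 100 draws). That correlation does not apply to groups that differ by LPS, so it is no measure for the observed one. The covariance was -0.213, against -0.00706 simulated, a difference of -0.205. With each LPS library used in 1 comparison only, the covariance was -0.205 to -0.202 and the correlation -0.742 to -0.726.

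**Figure D4:**
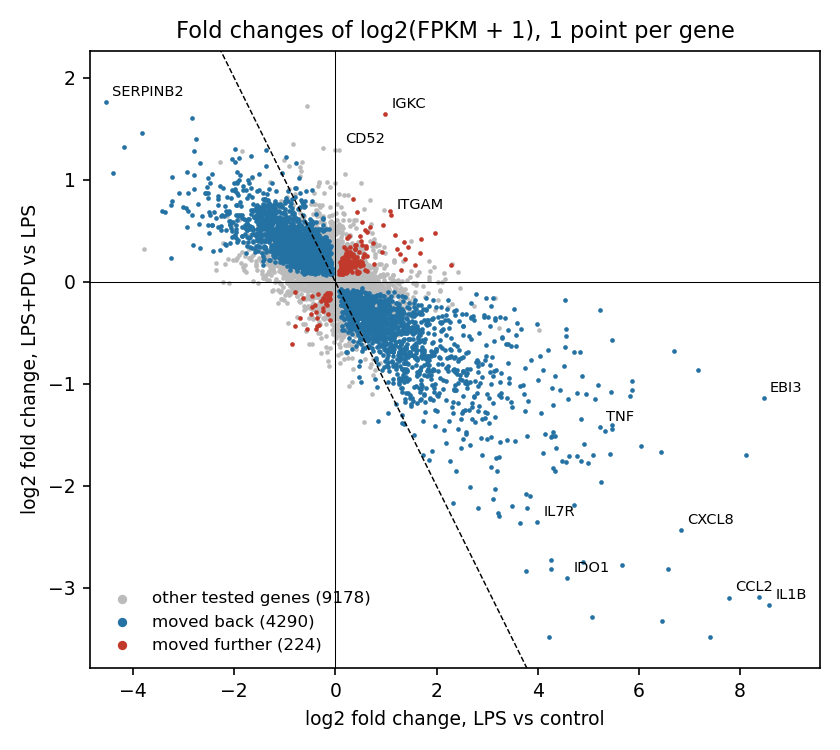
Log2 fold change of LPS+PD against LPS (y axis) against that of LPS against control (x axis), on the log2(FPKM + 1) scale, with 1 point per tested gene, blue for the 4290 genes moved back, red for the 224 moved further and a dashed line where both changes cancel. Genes raised most by LPS, such as IL1B (8.58 and -3.17), lie above the dashed line, where the rise with LPS was larger than the fall with PD.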

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

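Limma voom on recovered fragments and the restriction to protein-coding genes were chosen after the data were seen; the other alternatives were fixed before. All counts of called genes and lists stayed within 1.5 times the reported ones except as follows, and where the cause is not plain from the alternative it was not tested. An FPKM of at least 5, which tests 7807 genes, called 5929 genes for LPS vs control (3295 lower), and 2445 lower for LPS+PD vs control. An adjusted p below 0.01 called 3254 genes for LPS+PD vs LPS (1975 higher), 2851 genes moved back by PD, 91 moved further, 220 above both groups and 56 below both. An absolute log2 fold change of at least 1 called 1606 genes for LPS vs control (886 higher, 720 lower), 231 for LPS+PD vs LPS (35 higher, 196 lower) and 815 for LPS+PD vs control (533 higher, 282 lower), with 217 moved back, 0 moved further, 4 above and 0 below both groups and 9 of the 15 TNF and IL7 axis comparisons. Median-of-ratios scaling called 2058 genes higher for LPS+PD vs LPS, 149 moved further and 262 above both groups. By construction this scaling sets the median change between libraries near 0. It moved the median of all genes from -0.08 to -0.00144 for LPS vs control and from 0.07 to 0.00425 for LPS+PD vs LPS. With an estimated correlation 14, 12 and 7 lists were called in place of 27, 24 and 25; the cause was not tested. Fry called 32, 31 and 31 lists. It turned the direction of the alternative activation markers for LPS+PD vs LPS, whose median was 0.0206 (adjusted p = 0.0265); the cause was not tested.

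Leaving out each library in turn gave 8456 to 8996 genes for LPS vs control, 4178 to 5131 for LPS+PD vs LPS, 6793 to 7439 for LPS+PD vs control, 3552 to 4230 moved back, 157 to 244 moved further, 27 to 27, 24 to 24 and 24 to 25 lists, and 13 to 15 axis comparisons. Above both groups were 380 to 514 genes and below both 113 to 146. The lists that lost their call in this way were, for LPS+PD vs control, IL7 receptor signalling without control replicate 2 (adjusted p = 0.0528) and the mitochondrially encoded genes without control replicate 1 (adjusted p = 0.0737) or LPS+PD replicate 9 (adjusted p = 0.0626). Among single genes named, 20 values lost a call and 9 gained one over all alternatives, and 0 changed sign with a call. Robust and trend-free spread estimates and the fold threshold were not run for the list test. No paired analysis was possible because the groups share no replicate number.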

Other observations

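In the tests below, those of the mixture, of the shared LPS libraries, of transcript length and of the CC chemokines were chosen only after the result was seen. With PD, 516 genes were called above both LPS and control and 150 below both; 488 of the 516 (94.6%) and 130 of the 150 are protein-coding, against 79.6% of the tested genes. For the genes above both groups, scaling and reads of short noncoding RNA genes had first been set as explanations to test, the latter after the genes were seen. Both were dropped, so the protein-coding shares and the counts under another scaling are given as values only. Genes chosen after their values were seen include LYZ, the antibacterial lysozyme, at 169 ± 1.76 FPKM in control, 158 ± 12.2 with LPS and 301 ± 14.9 with LPS+PD (SD, n = 3), the collagen chain COL9A2 at 385, 407 and 604, PRKAR2B, a regulatory subunit of protein kinase A, at 8.10, 8.37 and 14.9, and the deaminase ADA2 at 4.06, 4.11 and 7.13. Among those below both were PLAC8 at 64.6, 67.1 and 40.3 and IGFBP4, which binds insulin-like growth factors, at 17.7, 15.5 and 9.55. The imbalance between these counts depended on the scaling. Under median-of-ratios scaling 262 genes were above both groups and 223 below both, and 237 of the 262 were among the 516. The signal recognition particle RNA RN7SL2, which has near-identical copies and lacks a poly(A) tail, was at 895, 941 and 1709.

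Across 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In each comparison the real split alone gave its count, so 1 of the 10 splits reached it. LPS vs control called 9059 genes, LPS+PD vs LPS 5037 and LPS+PD vs control 7489, while the highest other split called 0 in each, with limma at an adjusted p below 0.05 (258, 489 and 307 genes at an unadjusted p below 0.05). Each other split mixes libraries of both groups, which adds the difference between the groups to the spread. These counts therefore do not show how many genes unchanged groups would give.

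For the position of the LPS+PD libraries between control and LPS, 3 technical explanations were weighed. If LPS+PD RNA were a mixture of control-like and LPS-like RNA, each of the 297 genes induced at least 4-fold with an LPS mean FPKM of at least 5 would keep the same share of its LPS-induced FPKM. The median share kept was 44.5%, but the shares spread with an SD of 21.6 percentage points, 9.49 times the median standard error of a single gene's share, which argues against a mixture as the whole cause. The LPS libraries shared by both comparisons do not account for it, since the covariance of -0.213 lay below all simulated values (lowest -0.00812), and under quantile normalization 4043 genes were still moved back. An effect of PD on the LPS response is a hypothesis that remains, and without a PD-only group a separate effect of PD on these cells cannot be separated from it. The sources do not give vehicle, exposure time or whether replicates were separate cultures. A difference between the groups in any of these cannot be told apart from PD either, and the 3 tests do not address it.

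The fall of all 32 ribosomal protein genes with LPS was weighed against 3 technical explanations. With median-of-ratios scaling the list's median was -0.54 in place of -0.65, so scaling does not remove it. A match on total exon length was replaced by one on the length of the annotated principal transcript (median 1001 nt, range 505 to 3437), and the 84 nearest other protein-coding genes (up to 5 per gene) within 1.5 times that length and 1 log2 unit of mean FPKM had a median log2 fold change of -0.0787 (95% of 100000 random draws of 1 match per gene between -0.28 and 0.07), which argues against length or abundance as the whole cause. Fragments of these genes and of 514 ribosomal protein pseudogenes summed together fell by 0.64 on the log2 scale, which argues against a shift of reads to pseudogenes. The list call was lost with an estimated correlation, and a coordinated change of these transcripts with LPS may remain as a hypothesis.

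CC chemokine genes kept the smallest median share of their LPS-induced FPKM with PD, 12.1% over 10 induced genes, against 15.9% for inflammatory cytokines, 37.0% for interferon-stimulated genes and 51.8% for NF-kB target and feedback genes. CC chemokines had first been compared with NF-kB target and feedback genes alone, in a permutation test that did not match genes on their response and was replaced by the one given here. A candidate explanation was that genes with a larger LPS response keep less. Lists drawn at random from induced genes with a like LPS fold change had a median of 36.5% (95% of draws between 23.5 and 50.2%). The CC chemokines lay below with an adjusted p = 0.0163 (permutation test, 100000 draws, 11 lists). Fold changes were matched on the log2(FPKM + 1) scale, which understates the response of genes without control fragments, such as CCL1, CCL8 and CCL4L2. Some members also share reads, which random draws of genes do not reproduce. The low share was thus below that of genes with a like response on that scale, but response size is not excluded. The draws were not matched on the control level. Across genes the kept share had a Spearman correlation of 0.36 with the control mean FPKM and of -0.28 with the LPS fold change. Whether a low control level accounts for the low share was not tested. The single CC chemokine genes kept between 3.67 and 50.8%, and, chosen after their values were seen, CCL5 at 44.999% and CCL19 at 50.8% lay above the 44.5% median of all induced genes, so the low share was not a property of every member. None of the other 10 lists passed, with an adjusted p = 0.157 for inflammatory cytokines. CCL3 and CCL3L1, and CCL4 and CCL4L2, share reads, so the genes of this list are not independent, and a stronger effect of PD on most of these CC chemokines is a hypothesis.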
